A study of Rattus norvegicus with 6 samples.

How the data were processed

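RNA of liver endothelial cells was measured on 6 Affymetrix rat 230A expression arrays, 3 from control and 3 from cirrhotic Wistar rats. Per the labels, the cells were isolated by perfusing livers with collagenase, centrifuging and capturing the cells on antibody-coated magnetic beads, the RNA was extracted with Trizol and its quality was measured on a Bioanalyzer, and arrays were prepared after the manufacturer's manual. The labels describe the cirrhotic rats as adult males. How cirrhosis was induced, the target of the antibody, the sex of the control rats and the number of rats per array are not given in the sources used here. Groups and array numbers come from the sample titles, and 1 control array without a number in its title was called control 1.

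The deposited values are intensity on a linear scale, 1 signal per probe set and array, with the software and summary method not given in the sources used here. Their mean without the lowest and highest 2% was close to 400 on every array, so the authors' scaling was kept and the values were used as deposited. No detection calls and no scanner files were used here, and 0 further columns of values were left aside. A plain signal scaled this way reports each transcript relative to the rest of the array, so a change in total RNA per cell could not be seen.

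Values were turned into log2(signal + 16), where 16 is the 10th percentile of all values rounded to a whole number. The 57 control probe sets and the 40% of probe sets with the lowest mean log2(signal + 16) over all 6 arrays were left out, which removed 6347 probe sets and kept 9519. The threshold on this mean corresponds to a signal of about 127, and a probe set bright in only 1 group can fall under it. Cirrhotic and control were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a variance trend), with two-sided p-values adjusted by Benjamini-Hochberg over the 9519 probe sets and a threshold of 0.05. Where every array of the dimmer group lay at or under the highest of 27 bacterial control probe sets on that array, a bound on the fold was computed with the dimmer group set at that level, a rule chosen after seeing the data. Signal over background is what limits dim genes: the highest of these bacterial probe sets read between 21.7 and 49.9.

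Gene symbols were taken from the platform annotation table supplied with the data, dated earlier than the gene reference. Of 15866 probe sets, 12783 had 1 symbol, 312 had several and 2771 had none, and probe sets with several symbols named no gene. The gene identifiers of 12754 were found in the GRCr8 gene table and 0 symbols changed. No genome matched to the probe sets was given, so no positions are reported. Where probe sets of a gene disagreed, the choice followed the rules below.

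The following were fixed before the data were examined: the test, the filter, the alternatives, the rule for named genes and 34 gene lists (21 pathway lists and cell type lists for the endothelium and for other cells of the liver and blood). Lists were tested with camera at a preset correlation of 0.01 on 1 probe set per gene, the brightest, for the 29 lists with at least 5 measured genes, with Benjamini-Hochberg adjustment over the lists, and again with an estimated correlation and with fry. The genes named were, first, the 15 largest rises and 15 largest falls among genes with an adjusted p under 0.05 and no overlap between groups, taking the probe set with the smallest p. To these were added up to 4 members of each described list with the smallest p, on the list's probe set, and 24 genes of endothelial function, fibrosis and cell identity whatever their result. Of the 24, 18 were tested, 2 were too dim, and Ednrb, Tek, Cd34 and Stab2 had no probe set with a symbol of their own and were not analysed here. Cldn5 and other members falling under these rules are named with their list. Further lists in the closing section were written after the values had been seen.

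The arrays were checked for copies and grouping by correlation and principal components. RNA quality was checked by the ratio of 3' to 5' signal of actin, GAPDH and hexokinase. These ratios were compared with an exact permutation test, whose smallest two-sided p for 3 against 3 arrays is 0.1. Alternatives covered quantile normalization, median centring, other pseudocounts (1, and 126, the 40th percentile), no filter and a filter at 60%, variance models, array weights, probe sets with shared-sequence suffixes left out, array number as a block and each array left out in turn.

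The test was checked on simulated data with the real probe sets' means and spreads. Over 10 simulations with 200 of 9519 probe sets changed, 17.5% of 1.5-fold, 75.2% of 2-fold and 97.9% of 4-fold changes were recovered, and 7.30% of calls were false, above the nominal 5%. At an unadjusted p under 0.05, camera called 7 of 100 simulated lists without a change and 100 of 100 lists raised by 0.5. Noise was drawn independently for each gene, so these list counts do not cover lists whose genes move together. The 200 changed probe sets were far fewer than the 2421 called in the data, where the recovered and false shares may differ.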

Results

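Gene expression was measured in endothelial cells isolated from the livers of control and cirrhotic rats, with 3 arrays per group, to find which transcripts differ between the groups. Endothelial cells line the sinusoids and larger vessels of the liver. Each Affymetrix rat 230A array carried 15866 probe sets besides 57 control probe sets, and 9519 of them were bright enough to be tested. The trimmed mean signal lay between 399.2 and 399.6 on all 6 arrays, and the median signal between 177.7 and 200.9. The labels do not say whether an array held the RNA of 1 rat or of several, so p-values measure the spread between these arrays, and their number limits the precision.

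Cells from cirrhotic livers had lower signals of sinusoidal and general endothelial genes and higher signals of most measured extracellular matrix genes and stellate cell and myofibroblast markers. Stab1, a scavenger receptor of sinusoidal endothelium, fell by 1.64 on the log2 scale (SE 0.16, n = 3 per group), and Pecam1, an adhesion molecule of endothelial junctions, fell by 1.21 (SE 0.15). Col1a1, a chain of type I collagen, rose by 4.24 (SE 0.34), and the collagen-crosslinking enzymes Lox and Loxl1 rose by 4.02 (SE 0.26) and 4.88 (SE 0.38). Most measured markers of bile duct cells rose as well, the keratin gene Krt8 by 3.13 (SE 0.38) and Epcam by 3.25 (SE 0.63), or 4.02 without cirrhotic array 3. The keratin gene Krt19 had a difference of 2.07 (SE 0.76, adjusted p = 0.0826) and did not pass. All differences are on the log2(signal + 16) scale, where the size of a difference depends on the added 16 when 1 group is dim, as for Loxl1, with 2 of 3 control signals within the bacterial control probe sets.

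In limma's moderated test with Benjamini-Hochberg adjustment, 2421 of the 9519 probe sets differed between the groups at an adjusted p under 0.05, 1167 higher and 1254 lower in cirrhotic. The difference was at least 2-fold for 879 of them, 515 higher and 364 lower. The balance of directions depended on the scaling, since median centring gave 925 higher and 1480 lower, and 463 and 451 at least 2-fold. The called probe sets named 938 genes that were higher and 944 that were lower, and 1 gene was called in both directions by different probe sets. The groups did not overlap in 44.9% of the tested probe sets, against the 10% that chance gives for 3 against 3 arrays. Without control array 3 the count was 1341, and without cirrhotic array 1 it was 1366, against 2421 with all 6 arrays.

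**Figure D1:**
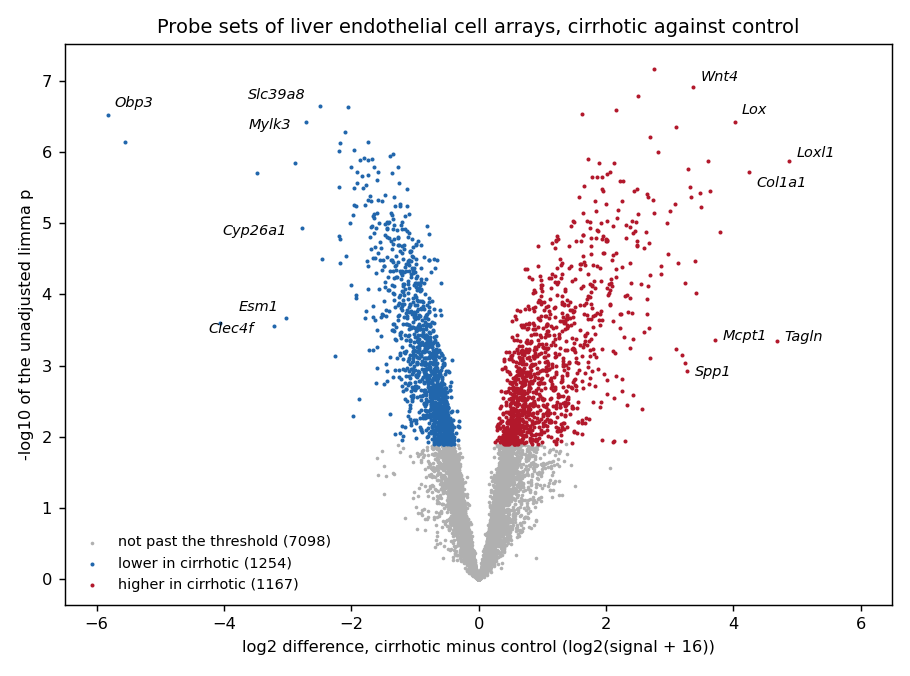
Each point is 1 of the 9519 tested probe sets, with the log2 difference between cirrhotic and control arrays (n = 3 each) on the horizontal axis and -log10 of the unadjusted limma p on the vertical axis. Red points were higher in cirrhotic (1167), blue points lower (1254) and grey points not past the threshold, and the named genes are from the largest rises and falls, whose plotted size depends on the added 16 where 1 group is dim.

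The arrays separated by group. Pearson's correlation across the tested probe sets lay between 0.912 and 0.967 for arrays of the same group and between 0.821 and 0.874 for arrays of different groups. The first principal component held 66.2% of the variance and separated the groups, and the second held 16.0%, with cirrhotic arrays 2 and 3 at opposite ends. No 2 arrays shared more than 47 identical values, so none was a copy of another. The ratio of 3' to 5' signal, which rises when RNA is degraded, was 1.44 ± 0.189 (SD, n = 3) in control and 1.25 ± 0.0185 in cirrhotic arrays for actin. For GAPDH it was 1.23 ± 0.142 and 1.14 ± 0.00955. For hexokinase it was 4.26 ± 2.87 and 2.65 ± 0.231, with control array 1 highest at 7.42. A two-sided exact permutation test gave p = 0.4 for actin and for GAPDH and p = 0.6 for hexokinase. The smallest p that 3 against 3 arrays allow is 0.1.

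The 15 largest rises included Loxl1, with a signal of 24.8 ± 21.9 in control and 1130 ± 399 in cirrhotic arrays (SD, n = 3, adjusted p = 0.000442), and Tagln, an actin-binding protein of contractile cells, which rose by 4.69 (SE 0.81, adjusted p = 0.00572). Its control signals lay far apart, and the rise was 5.65 without control array 1 and 3.75 without control array 3. Col1a2, Mfap4 and Ltbp2, which encode proteins of collagen and elastic fibres, rose by 3.49 (SE 0.31), 3.29 (SE 0.26) and 3.60 (SE 0.28). Wnt4, a secreted signalling protein, rose by 3.37 (SE 0.19) and Mmrn1, a protein of lymphatic endothelium and platelets, by 3.64 (SE 0.32). A2m, an acute phase protein of rat liver, rose by 3.79 (SE 0.40), Serpina6, the corticosteroid-binding globulin, by 3.40 (SE 0.41), and Lcn2, an iron-trapping protein of neutrophils and inflamed epithelium, by 3.41 (SE 0.47). The mast cell protease Mcpt1 rose by 3.71 (SE 0.64), or 4.51 without cirrhotic array 3, and the secreted phosphoprotein Spp1 by 3.28 (SE 0.66), or 2.56 and 4.06 without cirrhotic arrays 1 and 3. The tight junction protein Cldn3 rose by 3.33 (SE 0.29). In the control arrays the signals of Ltbp2 and Cldn3 lay within those of the bacterial control probe sets, and against that level they were at least 8.76-fold and at least 8.77-fold higher in cirrhotic.

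Obp3, an odorant-binding protein made in quantity by the male rat liver, had the largest fall, from a signal of 2295 ± 1066 to 21.2 ± 4.57 (adjusted p = 0.000355). The cirrhotic signals lay within the bacterial control probe sets, so the signal was at least 42.0-fold lower. Clec4f, a receptor of Kupffer cells, fell by 3.22 (SE 0.52), and Esm1, a proteoglycan secreted by endothelial tip cells, by 3.03 (SE 0.47), with a difference of -2.40 without control array 3. Apln, the ligand of the apelin receptor, fell by 2.09 (SE 0.24), Cyp26a1, which degrades retinoic acid, by 2.78 (SE 0.29), and the zinc transporter Slc39a8 by 2.50 (SE 0.15). Cyp2c11, the main male-specific cytochrome P450 of rat liver, fell by 2.26 (SE 0.42) and the major urinary protein Mup5 by 2.17 (SE 0.26). The remaining large falls were those of Mylk3, Plpp3, Hoxa5, Cdkn1c, Cidea, Cyp4b1 and Tinagl1, between -2.71 and -2.10, with adjusted p-values between 0.000361 and 0.00131.

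All 12 measured genes of the liver sinusoidal endothelial list fell, and all 12 also when adjusted over the list alone. Their median log2 difference was -1.19. Besides Stab1, these included the orphan receptor Gpr182 (-1.57, SE 0.14), the transcription factor Maf (-1.25, SE 0.14) and Bmp2, a ligand by which sinusoidal endothelium raises hepatocyte hepcidin (-1.36, SE 0.11). The hyaluronan receptor Lyve1 fell by 1.03 (SE 0.13) and the immunoglobulin receptor Fcgr2b by 0.75 (SE 0.09). The list passed camera, limma's competitive set test, with a preset correlation (adjusted p = 5.15e-09), and had an adjusted p = 0.363 with an estimated correlation.

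Of 21 measured pan-endothelial genes, 18 fell and 1 rose, and 19 fell and 1 rose when adjusted over the list alone (median -0.98, camera adjusted p = 2.92e-10, adjusted p = 0.0762 with an estimated correlation). Mmrn2 (-1.33, SE 0.12), the endoglin gene Eng (-1.12, SE 0.10) and the junctional protein Esam (-0.98, SE 0.11) fell. The vascular endothelial growth factor receptors Flt1 and Kdr fell by 1.63 (SE 0.19) and 0.82 (SE 0.11). Cldn5, a tight junction protein of vascular endothelium, was the exception and rose by 2.82 (SE 0.21), from a signal of 109 to 870. The endothelial nitric oxide synthase Nos3 fell by 0.70 (SE 0.14, adjusted p = 0.0111), a call that ended without control array 3 (adjusted p = 0.0509).

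**Figure D2:**
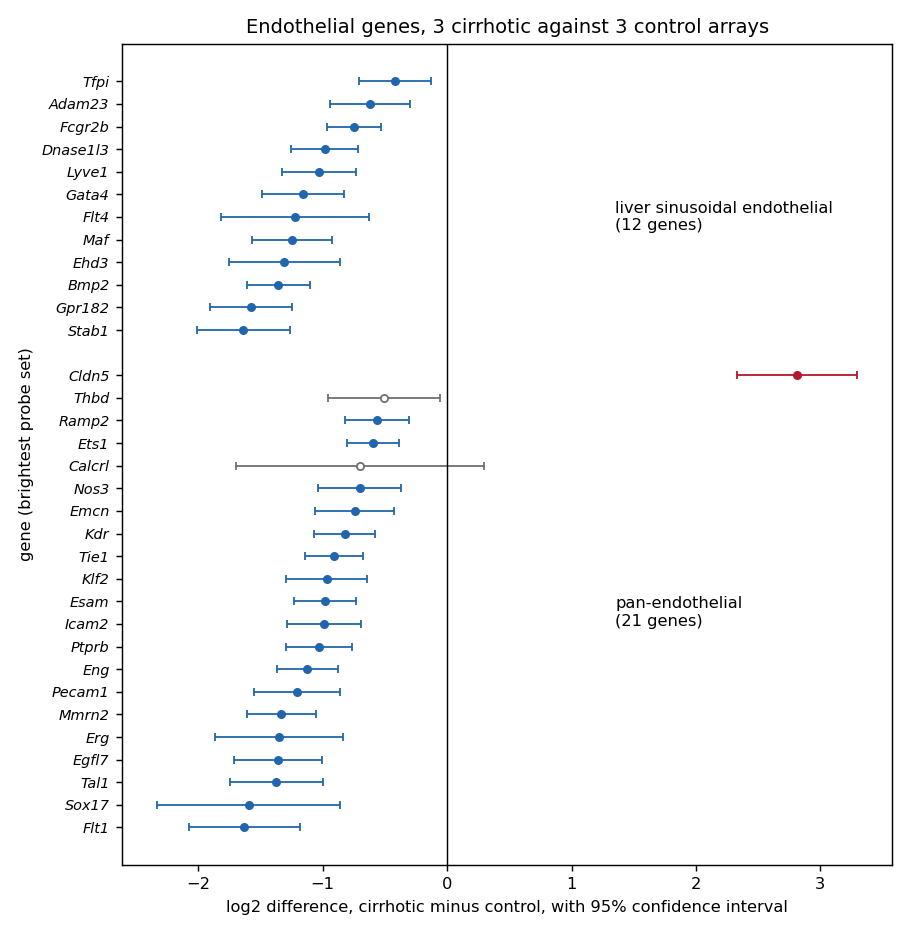
Each point is the log2 difference of 1 endothelial list gene between 3 cirrhotic and 3 control arrays, with its 95% confidence interval from limma; blue points fell, the red point rose and open grey points did not pass the threshold. Of the 33 genes, 30 fell, Cldn5 rose and 2 did not pass.

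In the angiogenesis list 14 of 29 measured genes fell and 6 rose, and 15 fell and 6 rose when adjusted over the list alone (median -0.43, camera adjusted p = 0.0154, adjusted p = 0.363 with an estimated correlation). The metalloprotease Adamts1 fell by 1.34 (SE 0.10) and the receptor Tie1 by 0.91 (SE 0.10). The ligands Vegfa and Vegfc rose by 1.59 (SE 0.26) and 1.96 (SE 0.22), and Col18a1, whose product releases endostatin, by 1.54 (SE 0.17). Vash1, an angiogenesis inhibitor of endothelium, had a difference of -0.18 (SE 0.12, adjusted p = 0.271) and did not pass the test. The transcription factor Hhex fell by 0.54 (SE 0.15, adjusted p = 0.0374), a call that ended without control array 1, control array 3 or cirrhotic array 1 (adjusted p = 0.115, 0.126 and 0.12). With genes that other lists also hold left out, a setting chosen after seeing the data, the angiogenesis list no longer passed (adjusted p = 0.109).

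The capillarisation and basement membrane list, of genes described in sinusoids that acquire a continuous wall, had 10 of 19 measured genes higher and 4 lower, and 11 higher and 4 lower when adjusted over the list alone (median 0.79, camera adjusted p = 0.0205, adjusted p = 0.484 with an estimated correlation). The laminin chains Lamb1 and Lama5 rose by 2.50 (SE 0.15) and 1.76 (SE 0.25), the adhesion receptor Selp by 1.94 (SE 0.21) and the basement membrane collagen Col4a1 by 1.03 (SE 0.15). The water channel Aqp1 fell by 0.95 (SE 0.14). Vwf, the von Willebrand factor gene, had a difference of 0.79 (SE 0.26, adjusted p = 0.0573), which passed without control array 1 (adjusted p = 0.0322) or cirrhotic array 3 (adjusted p = 0.0344). The list's adjusted p was 0.116 with genes of several lists left out and 0.076 with the stricter filter on dim probe sets.

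Of 36 measured extracellular matrix genes 27 rose and 1 fell, and 28 rose and 1 fell when adjusted over the list alone. Their median difference was 1.74 (camera adjusted p = 2.17e-11, adjusted p = 0.378 with an estimated correlation). Besides Col1a1, Lox and Loxl1, the type V collagen gene Col5a1 rose by 1.94 (SE 0.17). Col3a1 had a difference of 0.60 (SE 0.49, adjusted p = 0.402) on a dim probe set. Stellate cell and myofibroblast markers moved with them, with 12 of 19 genes higher and 1 lower, and 13 higher and 1 lower when adjusted over the list alone (median 1.29, camera adjusted p = 1.25e-05, adjusted p = 0.378 with an estimated correlation). The pericyte genes Pdgfrb and Rgs5 rose by 2.68 (SE 0.29) and 2.87 (SE 0.36), the proteoglycan gene Dcn by 2.00 (SE 0.22) and the tropomyosin gene Tpm1 by 2.12 (SE 0.16). The probe set of Acta2, the smooth muscle actin of activated stellate cells, was too dim to be tested, with signals of 17.6 ± 3.12 in control and 62.3 ± 31.1 in cirrhotic arrays.

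Marker genes of other cell types were measured in both groups. Among 12 cholangiocyte markers 8 rose and none fell, and 10 rose when adjusted over the list alone (median 2.22, camera adjusted p = 0.000121, adjusted p = 0.54 with an estimated correlation). Krt18 rose by 2.46 (SE 0.26) and Cdh1 by 3.10 (SE 0.56), or 3.70 without cirrhotic array 3. Krt19 did not pass (adjusted p = 0.0826) and read 70.0 on cirrhotic array 3, within the control signals of 39.0 to 91.4. Without that array its difference was 3.08 (adjusted p = 0.000707). The Krt7 probe set was too dim to be tested (48.4 ± 7.65 and 51.6 ± 25.2). Of 34 hepatocyte markers 10 rose and none fell, and 10 rose when adjusted over the list alone (median 0.38, camera adjusted p = 0.00485, adjusted p = 0.698 with an estimated correlation). The apolipoprotein gene Apoa1 rose by 2.59 (SE 0.43) and the hepcidin gene Hamp by 1.22 (SE 0.24). The albumin gene Alb had high signals in both groups and did not pass (11075 ± 577 in control and 12728 ± 1255 in cirrhotic, adjusted p = 0.142). Its signal was the highest of any probe set on each cirrhotic array, and at the top of the range a rise may not show. The hepatocyte list did not pass without cirrhotic array 3 (median 0.16, adjusted p = 0.337).

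Among 17 Kupffer cell and macrophage markers 2 rose and 2 fell, and 6 rose and 2 fell when adjusted over the list alone (median 0.40, camera adjusted p = 0.308). Laptm5 rose by 1.40 (SE 0.28) and the lysozyme gene Lyz2 rose too, a call that ended without control array 3 (adjusted p = 0.0546), while Clec4f, named above, and the haem oxygenase gene Hmox1 fell, Hmox1 by 1.06 (SE 0.28), and the call of Hmox1 ended without control array 2 or 3 (adjusted p = 0.0971 and 0.102). The pan-macrophage gene Cd68 had a difference of 0.40 (SE 0.38, adjusted p = 0.472). Of 19 T and NK cell markers 8 rose, and 8 rose and 1 fell when adjusted over the list alone (median 0.28, camera adjusted p = 0.0631). The T cell receptor chains Cd3e and Cd3g rose by 2.11 (SE 0.24) and 2.04 (SE 0.27), and the Cd3d probe set was too dim to be tested (40.1 ± 11.4 and 39.9 ± 13.1). Without cirrhotic array 3 both lists passed camera at the preset correlation, the macrophage list at an adjusted p of 0.013 and the T and NK cell list at 0.00138. The latter passed without control array 2 too (0.0156). With all arrays and an estimated correlation, the adjusted p was 0.825 for the macrophage and 0.746 for the T and NK cell list.

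Cirrhotic array 3 stood apart from cirrhotic arrays 1 and 2 in these marker lists. All 12 cholangiocyte markers, all 17 macrophage markers and 18 of 19 T and NK cell markers had their lowest cirrhotic signal on it, with median log2 differences from the mean of the other arrays of -1.71, -1.02 and -0.97. All 34 hepatocyte markers had their highest cirrhotic signal there, with a median difference of 0.99. Of the mast cell markers 3 of 4, and of the neutrophil markers 2 of 2, also had their lowest cirrhotic signal there, with median differences of -1.11 and -1.25. The matrix and stellate lists differed by -0.24 and 0.17. Without this array 2472 probe sets passed the test, 981 of them at least 2-fold.

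**Figure D3:**
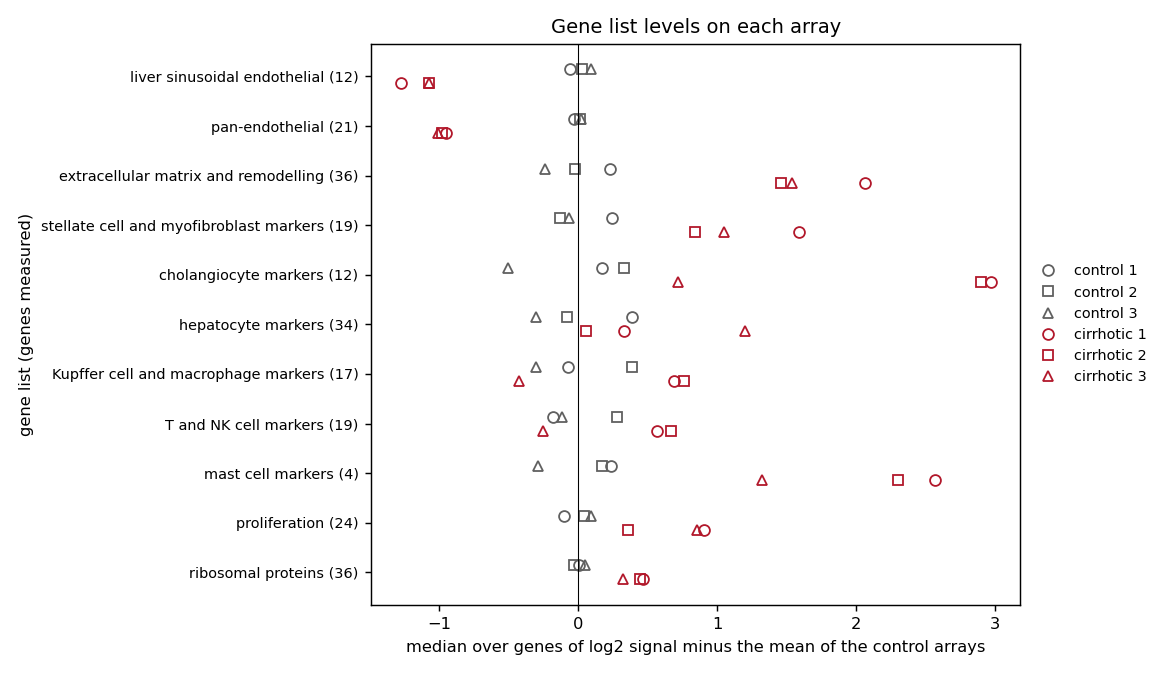
Each symbol is the median over the measured genes of a list (number in brackets) of the log2 signal on 1 array minus the mean of the control arrays, grey for control and red for cirrhotic. Both endothelial lists lie between -1.28 and -0.95 on the cirrhotic arrays, whereas cirrhotic array 3 parts from the other arrays in the cholangiocyte (0.72), hepatocyte (1.20), macrophage (-0.43) and T and NK cell (-0.25) lists.

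Small marker lists had few bright genes. Mast cell markers had 3 of 4 genes higher and 1 lower over all probe sets and adjusted over the list alone, with the carboxypeptidase Cpa3 up by 2.67 (SE 0.43) and the receptor Kit down (-1.36, SE 0.16). The call of the tryptase gene Tpsb2 ended without control array 3 or cirrhotic array 1 (adjusted p = 0.0582 and 0.0602). Of 5 lymphatic endothelial and mesothelial markers 3 rose, and 4 when adjusted over the list alone (median 1.77, camera adjusted p = 0.0072, adjusted p = 0.484 with an estimated correlation). The list genes Prox1 and Pdpn rose by 1.47 (SE 0.22) and 1.77 (SE 0.28). The gene added when adjusted over the list alone was Krt19, which is also in the cholangiocyte list, so these counts do not single out lymphatic endothelium. Both measured B and plasma cell genes, both erythroid genes and 1 of 2 neutrophil genes rose, and adjusted over the list alone 2 of 2 rose in each of these lists. The calls of the B and plasma cell genes Cd37 (1.30, SE 0.35) and Sdc1 (0.81, SE 0.20) ended without any of control arrays 2 and 3 and cirrhotic array 1, with adjusted p-values from 0.0581 to 0.114, and that of Cd37 also without control array 1 (0.0569) or cirrhotic array 2 (0.0704). The call of the haemoglobin gene Hbb (2.43, SE 0.56, and 3.10 without cirrhotic array 3) ended without control array 1 or 3 or cirrhotic array 1 (adjusted p = 0.056, 0.0694 and 0.0684), and that of the transferrin receptor gene Tfrc (1.02, SE 0.30) without any 1 of the control arrays or cirrhotic array 1 (from 0.0586 to 0.128). Neither of 2 platelet genes passed in either way.

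Proliferation genes rose in 15 of 24 cases with none falling, and in 17 when adjusted over the list alone (median 0.77, camera adjusted p = 1.25e-05, adjusted p = 0.378 with an estimated correlation). The topoisomerase gene Top2a rose by 1.44 (SE 0.22) and the mitotic kinase gene Cdk1 by 1.49 (SE 0.27). Of 36 ribosomal protein genes 27 rose and none fell, and 34 rose when adjusted over the list alone, with a small median difference of 0.37 (camera adjusted p = 2.17e-11, adjusted p = 0.378 with an estimated correlation). Rpl12 rose by 0.77 (SE 0.11). Oxidative phosphorylation genes rose in 11 of 50 cases, also in 11 when adjusted over the list alone (median 0.29, camera adjusted p = 2.25e-05, adjusted p = 0.604 with an estimated correlation), with Atp5f1e up by 0.80 (SE 0.13).

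In the immediate early and heat shock list 12 of 29 genes fell and 5 rose, and 14 fell and 5 rose when adjusted over the list alone (median -0.47, camera adjusted p = 0.0154, adjusted p = 0.627 with an estimated correlation). Egr1 and Junb fell by 0.65 (SE 0.08) and 0.71 (SE 0.10), the small heat shock protein gene Hspb1 by 1.01 (SE 0.14), and Myc rose by 1.36 (SE 0.19). Cholesterol synthesis genes rose in 2 of 16 cases and in 0 adjusted over the list alone (median 0.51, camera adjusted p = 0.0154, adjusted p = 0.627 with an estimated correlation). Both of these genes had fragile calls, since that of Fdps (0.91, SE 0.28) ended without any 1 of the control arrays or cirrhotic array 1 (adjusted p from 0.0656 to 0.148) and that of Msmo1 (0.55, SE 0.17) without any 1 array but cirrhotic array 2 (from 0.0622 to 0.161). Fatty acid handling genes rose in 5 of 28 cases and fell in 1, and rose in 3 and fell in 1 adjusted over the list alone (median 0.30, camera adjusted p = 0.0399, adjusted p = 0.378 with an estimated correlation). Lipoprotein lipase, Lpl, rose by 2.70 (SE 0.19) and hormone-sensitive lipase, Lipe, fell by 1.80 (SE 0.14). Without cirrhotic array 3 these 3 lists did not pass (adjusted p = 0.0758, 0.139 and 0.169), nor did the fatty acid list without control array 2 (0.0594). The cholesterol list did not pass with the stricter filter (0.0514) or array weights (0.0919), and the fatty acid list did not with either (0.06 and 0.0862) or with genes of several lists left out (0.0894).

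Vasoactive mediators changed in both directions, with 10 of 34 genes higher and 8 lower over all probe sets and 12 higher and 9 lower when adjusted over the list alone (median 0.00, camera adjusted p = 0.91). The natriuretic peptide receptor Npr1 and the cannabinoid receptor Cnr2 fell by 1.73 (SE 0.13) and 1.44 (SE 0.14). Ptgs2, the inducible cyclooxygenase, and the phospholipase Pla2g4a rose by 2.50 (SE 0.24) and 1.66 (SE 0.20). The endothelin gene Edn1 (0.48, SE 0.19, adjusted p = 0.0978) and the caveolin gene Cav1 (0.26, SE 0.18, adjusted p = 0.34) did not pass, though Edn1 passed without cirrhotic array 1 (adjusted p = 0.037).

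The TGF-beta and BMP list had 5 of 31 genes higher and 8 lower, and 8 higher and 10 lower when adjusted over the list alone (median 0.05, with camera's direction downward, adjusted p = 0.755). Bmp6 fell by 1.59 (SE 0.13). Of 36 scavenging and lysosome genes 4 rose and 11 fell, and 4 rose and 13 fell when adjusted over the list alone (median -0.22, camera adjusted p = 0.0529, and 0.0135 without cirrhotic array 1). The sulphatase gene Arsb fell by 1.36 (SE 0.13) and the endocytic adaptor gene Dab2 by 0.99 (SE 0.13). In the coagulation list 4 of 15 genes rose and 2 fell, and 8 rose and 3 fell when adjusted over the list alone (median 0.33, camera adjusted p = 0.0845, and 0.025 without cirrhotic array 3). Tissue factor, F3, rose by 2.02 (SE 0.22) and the inhibitor gene Tfpi2 fell by 1.24 (SE 0.19).

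Inflammation genes rose in 6 of 30 cases and fell in 5, with the same counts adjusted over the list alone (median 0.10, camera adjusted p = 0.425, and 0.0454 without cirrhotic array 3), and Il1a fell by 1.65 (SE 0.16). Interferon response genes rose in 2 of 26 cases and fell in 5, or in 2 and 6 adjusted over the list alone (median -0.29, camera adjusted p = 0.0631), and passed without control array 1 or 3 or cirrhotic array 2 (adjusted p = 0.0329, 0.0454 and 0.00957). Ifit3 fell by 1.74 (SE 0.24) and Bst2 by 1.06 (SE 0.12). In the complement list 3 of 18 genes rose and 1 fell, or 4 and 1 adjusted over the list alone (median 0.54, camera adjusted p = 0.146, and 0.0282 without cirrhotic array 2), with C1s up by 1.79 (SE 0.28). MHC class II genes rose in 1 of 12 cases and in 0 adjusted over the list alone (median 0.39, camera adjusted p = 0.0939, and 0.00383 without cirrhotic array 3). The MHC list gene that rose, Ifi30 (0.63, SE 0.16), lost its call without any 1 array but cirrhotic array 3 (adjusted p from 0.0627 to 0.0956).

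Among the remaining pathway lists, 9 of 21 glycolysis and hypoxia genes rose and 1 fell, or 9 and 4 adjusted over the list alone (median 0.20, camera adjusted p = 0.115, and 0.0425 without cirrhotic array 3). Pfkfb3 fell by 1.59 (SE 0.15) and the oxygen-sensing hydroxylase gene Egln3 rose by 1.79 (SE 0.24). Of 22 drug metabolism genes 2 rose and 2 fell, and of 28 oxidative stress genes 3 rose and 4 fell, with the same counts adjusted over the list alone (medians 0.33 and 0.14, camera adjusted p = 0.624 and 0.398). Gstp1, a glutathione transferase, fell by 1.17 (SE 0.13) and the metallothionein gene Mt2A by 1.20 (SE 0.14). The calls of the higher drug metabolism genes Cyp1b1 and Gsta3 each ended without any 1 of 5 arrays. Their adjusted p-values were then from 0.0572 to 0.105 and from 0.0698 to 0.113. Gsta3 also lost its call with quantile normalization (0.0638), median centring (0.0559) and no filter (0.0651). Of 25 unfolded protein response genes 4 rose and 3 fell, with the same counts adjusted over the list alone (median 0.05, camera adjusted p = 0.624).

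In all, 15 of 29 tested lists passed camera with the preset correlation, 11 upward and 4 downward, and 0 passed with an estimated correlation, where 3 had an unadjusted p under 0.05. Fry, which asks whether a list's genes move on balance in 1 direction, passed 12 lists, 10 of them among the 15. It did not pass the immediate early, oxidative phosphorylation, cholesterol, hepatocyte and cholangiocyte lists (adjusted p = 0.167, 0.0901, 0.173, 0.323 and 0.0563) and passed the coagulation and scavenging lists (0.0294 each). Among lists that did not pass, array weights brought past the threshold the T and NK cell (0.0144), macrophage (0.0393), interferon (0.0393), coagulation (0.0393), MHC class II (0.0447) and glycolysis (0.0434) lists. Without the filter the scavenging (0.0211), T and NK cell (0.0278), MHC class II (0.0323), coagulation (0.0323) and interferon (0.0441) lists passed. Other splits of the 6 arrays gave up to 17 lists in the preset test.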

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

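Both results in this part come from measurements outside the comparison of tested probe sets and were looked at after the main results were seen. The 3 GAPDH control probe sets, printed on the array to monitor RNA quality, were higher on every cirrhotic array than on any control array, with a median log2 difference of 0.77. The difference was 0.69 after median centring and 0.83 after quantile normalization. The 3' probe set read 3629 ± 80.3 in control and 5778 ± 320 in cirrhotic arrays (SD, n = 3).

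Among the 6347 probe sets left out as dim, 68 were at least 3 times higher on every cirrhotic array than on any control array and lay above the bacterial control probe sets on each cirrhotic array, against 2 that were lower by the same measure. Of the 68, 56 named 1 gene and 8 belonged to a fixed list. They included the matrix genes Tnc (16.9 ± 3.81 in control, 251 ± 240 in cirrhotic) and Postn (6.93 ± 1.30 and 197 ± 204), whose cirrhotic means without cirrhotic array 1 were 113 and 78.7, the mast cell chymase Cma1 (6.43 ± 0.737 and 426 ± 302), the lipoprotein receptor Vldlr (27.8 ± 8.25 and 338 ± 53.6), the branched-chain aminotransferase Bcat1 (9.07 ± 0.85 and 296 ± 64.8) and Cyp2c12, a female-predominant cytochrome P450 of rat liver (17.9 ± 6.77 and 365 ± 25.9). These genes were chosen after their values were seen. The 2 lower probe sets named the potassium channels Kcnd3 (171 ± 14.5 and 21.0 ± 2.90) and Kcnj15 (269 ± 65.9 and 45.5 ± 11.8). The test for an array far from its group needs at least 4 arrays and was not run.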

How the results depend on the processing

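The alternatives were planned before the data were examined, except those named as added. No call reversed, and 100% of the 2421 called probe sets kept their direction in every refit that tested them. With array weights 3772 probe sets passed (1818 higher, 1954 lower). At the 40th percentile pseudocount 579 were at least 2-fold different and 228 at least 2-fold lower, and with the stricter filter 304 were at least 2-fold higher and 7 lists shifted up. No filter gave 1134 at least 2-fold. Leaving out each array in turn gave 1341 to 2472 probe sets (627 to 1256 higher, 694 to 1216 lower), 676 to 981 at least 2-fold and 15 to 17 lists. Numbers 2 and 3 occur in the titles of both groups. With the number as a replicate block on these 4 arrays 908 probe sets passed (497 higher, 411 lower), 794 at least 2-fold, and 18 lists. Fewer arrays enter that fit. The differences between arrays 2 and 3 did not run together in control and cirrhotic (correlation -0.106). This single value does not exclude that same-numbered arrays share a day or preparation. Camera with an estimated correlation called 0 lists (0 up, 0 down) against 15. With genes of several lists left out, an added alternative, 14 passed. For these counts the cause was not tested unless named. Of 144 called named probe sets, between 2 and 17 lost their call when 1 array was left out. The added background bound left Cldn3 at 3.13, Ltbp2 at 3.13 and Obp3 at -5.39. The dim-signal floor limits folds of low probe sets, not those of bright endothelial genes.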

Other observations

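The lists and tests of this part were written after the gene values had been seen, except the counts over other splits of the arrays. In a list of 16 measured retinoid genes, tested without the filter on dim probe sets, 5 fell and 1 rose. Besides Cyp26a1, the related retinoic acid hydroxylase Cyp26b1 fell by 1.98 (SE 0.53, limma adjusted p = 0.0453), the retinoic acid receptors Rarb and Rarg by 0.91 (SE 0.15) and 0.99 (SE 0.20), and the retinal reductase Dhrs3 by 0.98 (SE 0.12), while Rarres2, the chemerin gene, rose by 1.42 (SE 0.28). The call of Cyp26b1 ended without any 1 array but cirrhotic array 3 (adjusted p from 0.06 to 0.12), that of Rarg without any 1 of the control arrays or cirrhotic array 1 (from 0.0544 to 0.0726) and that of Rarres2 without control array 2 or 3 or cirrhotic array 1 (0.056, 0.0668 and 0.0599), and without each of the control arrays and cirrhotic array 1 only 3 retinoid genes fell. Among 14 measured genes of semaphorins, ephrins and Wnt signalling 5 fell and 4 rose. The semaphorins Sema6a and Sema6b fell by 1.70 (SE 0.18) and 1.77 (SE 0.14), the Wnt receptor Fzd4 by 1.57 (SE 0.11) and the ephrin Efna1 by 1.09 (SE 0.17). The ephrin receptor Ephb4 fell by 0.95 (SE 0.19), a call that ended without control array 1 or 3 or cirrhotic array 1 (adjusted p = 0.0503, 0.0669 and 0.0677). The Wnt ligand Wnt4 and the secreted Wnt modulators Sfrp1 (1.84, SE 0.31) and Dkk3 (1.26, SE 0.21) rose. The other gene counted as higher, the semaphorin Sema3a, had cirrhotic signals within the bacterial control probe sets on 2 of 3 arrays, and its call ended without any 1 array but cirrhotic array 3 (adjusted p from 0.0892 to 0.125).

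Hepatic acute phase genes were higher in 9 of 16 cases with none lower (median 1.48, without the filter), among them the lipopolysaccharide-binding protein Lbp at 2.09 (SE 0.28). On cirrhotic array 3 the signal was the highest of the cirrhotic arrays for 15 of the 16, with a median log2 difference of 0.81 from the other arrays. Without that array 7 were higher (median 1.21), without control array 2, control array 3 or cirrhotic array 1 5 were, and without cirrhotic array 2 13 were. Of 10 genes with male-predominant expression in rat liver 3 fell and none rose (median -0.77), namely Obp3, Mup5 and Cyp2c11, while Cyp2c13 had a difference of 0.08 (SE 0.32, adjusted p = 0.895) and Cyp3a2 of -0.57 (SE 0.82, adjusted p = 0.699). The differences of Hsd3b5, Sult1e1 and Cyp2a2 were -0.12, -0.10 and 0.39, and those of Car3 and Sult1c3 were -1.52 (SE 0.51, adjusted p = 0.0881) and -0.98 (SE 0.53, adjusted p = 0.266). Without the filter the call of Cyp2c11 ended without control array 3 or cirrhotic array 1 (adjusted p = 0.0551 and 0.0582), and without cirrhotic array 3, where 9 of the 10 had their highest cirrhotic signal, 5 fell, with Car3 and Sult1c3 added (adjusted p = 0.012 and 0.017). Of 6 female-predominant genes Cyp2c12 and Serpina6 rose. Cyp2a1 (0.40, SE 0.41, adjusted p = 0.568) and Prlr (0.06, SE 0.25, adjusted p = 0.909) did not pass, and A1bg and Sult2a1 lay within the bacterial control probe sets on all arrays.

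The 30 falling endothelial genes may reflect fewer endothelial cells per preparation or a change within those cells. A lower share alone would move all of them equally only if other cells held little of these transcripts and probe sets responded in proportion. It would also need the same kinds of endothelial cell in both groups, and these conditions were not tested. The differences varied beyond their standard errors (excess SD 0.290 over genes without Cldn5, which was left out after its value was seen, and 0.518 with it). Without those conditions this spread does not decide whether a lower share was the whole cause. The 3' to 5' ratio of actin and GAPDH was not higher in cirrhotic (mean log2 difference -0.15), which argues against more degraded RNA, and the median fall of -0.99 after quantile normalization argues against array scaling. A lower share as all or part of the cause and a change within the endothelial cells stay open, since bulk arrays cannot separate them.

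The rise of matrix genes and stellate markers may come from other cells in the preparation. The medians of 5 marker lists (stellate, cholangiocyte, macrophage, hepatocyte, T and NK cell) differed more than chance allocation of genes gives (permutation p = 2e-05). That test treats genes as independent, but genes within these lists moved together (estimated correlation from 0.280 to 0.835). It therefore does not decide whether cells of every other type increased in equal measure. For 7 quiescent stellate markers the median was 0.25 against 1.70 for 44 matrix genes, and the permutation p of 0.066 does not decide whether stellate cells of the kind in control preparations increased. Activated stellate markers, all 13 of which are also in a list fixed earlier, had a median of 2.04 without the filter on dim probe sets. They ran from Loxl1 at 4.88 and Col1a1 at 4.24, with a cirrhotic signal of 5380.0 for Col1a1, to Actg2, Timp1 and Cnn1, which did not pass (0.96, 0.83 and 0.05). Acta2 and Myh11 (1.15 and 1.01), too dim for the main test, were called only without the filter. Their calls ended without any 1 array but cirrhotic array 3 (limma adjusted p from 0.058 to 0.155). The control signals of Acta2 lay within the bacterial control probe sets, and against that level it was at least 1.30-fold higher in cirrhotic. Activated myofibroblasts carried through the bead capture and a switch of the captured cells to matrix genes cannot be told apart on bulk arrays.

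In the hepatocyte list fixed earlier 10 of 34 genes rose and none fell, while falls were called for 3 of 10 male-predominant genes. The medians were -0.77 for male-predominant, 1.48 for acute phase and 0.24 for other hepatocyte genes. A permutation test of these medians gave p = 1e-05, the smallest 100000 resamples can give, but carries no weight, since the first 2 lists were written after some of their genes had been seen to move. In a test chosen after that one, over the 34 measured genes of the hepatocyte list fixed earlier, the differences varied beyond their standard errors (excess SD 0.613, and 0.682 over the 22 with control signals between 500 and 5000), which argues against a changed amount of hepatocyte RNA as the whole cause. RNA of female rats on the cirrhotic arrays, against the labels, would lower all male-predominant genes strongly. Against it, 4 of the 10 have a 95% interval above -2, among them Cyp2c13, whose probe set carries a shared-sequence suffix. The median of -0.77 lay between -1.46 (without cirrhotic array 3) and -0.08 (without cirrhotic array 2) when 1 array was left out. With an upper quartile of -0.11 and 3 genes under -2, the 10 genes do not exclude RNA of female rats. A shift of the hepatocytes of cirrhotic males toward acute phase and female-pattern expression, seen here through hepatocyte RNA in the preparations, is a hypothesis that was not tested.

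The 6 arrays can be split into groups of 3 in 10 ways, too few for a share under 0.05. The real split gave 2421 probe sets and 879 at least 2-fold, and the highest other split gave 0 for each in limma, with up to 361 probe sets at an unadjusted p under 0.05 against 3804. Every other split mixes control and cirrhotic arrays, so the difference between the groups adds to the spread on each side. The 0 is therefore no evidence against a chance result. For gene lists the real split gave 15 and the highest other 17, and 4 of the 10 splits, the real one included, gave 15 or more.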
